A study of Equus caballus with 21 samples.

How the data were processed

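Gene expression was measured by RNA sequencing in horse endometrium collected by uterine biopsy on day 12 of pregnancy and on day 12 of the estrous cycle. Per the labels, luminal epithelium, glandular epithelium and stroma were cut out of the biopsies by laser capture microdissection, and each library came from 1 captured compartment of 1 biopsy. The libraries were made from very small amounts of RNA with a kit for single cells and sequenced as single-end reads in 2 lanes of 1 flow cell, per the labels' protocols. A number of libraries received an extra round of amplification, and the labels do not say which. The mares were warmbloods whose ovulation was induced with human chorionic gonadotropin, and the pregnant biopsies followed insemination.

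The letter in each library's label names the mare, and the same letter in both states and in several compartments marks the same animal. The labels hold 5 mares (B, C, J, M and U), whereas the design text of the series speaks of 6, and the letters were used as given. There were 5 cyclic and 4 pregnant luminal libraries, 4 cyclic and 4 pregnant glandular libraries, and 2 cyclic and 2 pregnant stromal libraries. Mare J gave a cyclic luminal library and no other. The 2 states of the stroma shared mare M alone.

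Reads were trimmed with Trimmomatic 0.32.2 and aligned with HISAT2 2.0.3, per the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited a table of raw read counts for 24942 gene IDs in the 21 libraries, with whole numbers and a different total in each library. The authors also deposited 2 tables of signal in CPM, counts scaled to library size, of which 1 held 10307 genes in all 21 libraries and the other 10410 genes in 19 libraries. The table of 19 libraries lacked the pregnant luminal and the cyclic glandular library of mare M, and 10233 genes stood in both tables. Each deposited signal value equalled the deposited count divided by a constant of its library, with relative deviations of at most 5.8e-15. The columns summed to between 701256 and 2193373 in the table of 21 libraries, so the tables used an effective library size, and they served here only as alternatives. Their names speak of a trended dispersion, and the name of the 21-library table also speaks of removed duplicates. Whether duplicates were removed before counting is not given in the sources used here.

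Gene symbols came from a RefSeq gene table of a horse assembly, matched by Entrez gene ID and used for names only. Of the 24942 IDs, 21420 (85.9%) matched, as did 92% of the 15265 IDs with a count in any library. Unmatched IDs carried 1.38% to 7.7% of the counts of a library and are printed as IDs. Counts of near-identical gene copies, multigene families and overlapping genes are uncertain, because the rule for shared reads is not given. The kit was not stated to mark the strand, so antisense reads could not be told apart.

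Total counts ran from 136259 to 1467510 per library. A gene with no count in a group was given a floor of 3 counts over the group's summed effective library size, and a ratio with 1 to 3 counts in a group was given its exact (Clopper-Pearson) 95% counting interval. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

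All analyses ran in R 4.3.3. The main tests used edgeR 4.0.16 on the raw counts with quasi-likelihood F-tests (two-sided), trimmed mean of M values (TMM) scaling and filterByExpr (minimum count 10, minimum total count 15). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and every adjusted p of a gene in the text comes from this test unless another tool is named. Levels are given as CPM of the TMM-scaled library size, as mean ± SD with n mares, and log2 fold changes as estimate ± SE. The SE was derived as the absolute estimate divided by the square root of the test's F value. It therefore rests on spread shared between genes, does not measure the spread over mares, and is unreliable for very small estimates. Summed marker levels, the most abundant genes and the levels of gland transcripts in single stromal libraries are instead CPM of the counts without the ribosomal RNA genes, without TMM scaling, so they do not compare with the other levels. Pregnant and cyclic libraries were compared within each compartment, without a block. The difference of the pregnancy effect, glandular minus luminal, was tested in the 16 epithelial libraries of mares B, C, M and U with the biopsy as a block. For differences between compartments, counts were summed per mare and compartment and the mare was a block. The deeper library of a mare thus weighed more in its sum. In mare C this was the cyclic luminal library (1382614 against 375564 counts) but the pregnant glandular one (1467510 against 600512). In mare M the luminal libraries held 324704 cyclic and 136259 pregnant counts, and the glandular ones 222623 and 792665. In mare U the luminal ones held 634559 and 363394, and the glandular ones 360167 and 502583 (330206 and 325144 without ribosomal RNA genes). The luminal sums of mares C, M and U thus leaned to the cycle, and the glandular sums of C and M to pregnancy. In mare B the cyclic glandular library was the deeper one (1079351 against 486316). In the stromal sum of mare M the pregnant library was the deeper one (1175127 against 138441). State was therefore not balanced between the summed compartments, and the mare as block did not remove this. Luminal and glandular epithelium were compared in 4 mares, and stroma was compared with each epithelium in 3 mares, over the biopsies that had stroma. In these comparisons and in the difference of effects the estimated prior degrees of freedom were infinite, so the test took almost no account of the spread of the single gene. For pregnancy they were 371.8 in luminal epithelium, 79.87 in glandular epithelium and 37.77 in stroma, against 7, 6 and 2 residual ones. Those tests therefore also gave little weight to the spread of the single gene. The common biological coefficient of variation was 1.18 in luminal epithelium, 1.08 in glandular epithelium and 1.38 in stroma.

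The 32 gene lists covered prostaglandins, steroid receptors and metabolism, interferon-stimulated genes, antigen presentation, complement, uterine secretory proteins, transporters, adhesion, junctions, matrix, WNT signalling, growth factors, cell division, the secretory pathway, oxidative phosphorylation, lipid metabolism, stress genes, ribosomal proteins, gland-associated genes, mitochondrially encoded genes and markers of cell types. Lists with 5 or more tested genes were tested with camera (limma 3.58.1, two-sided) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. An estimated correlation and the fry test stood beside it. Of the 32 lists, 26 reached 5 tested genes in a comparison. Lists, designs, most of the other settings and the rule for named genes were written before the data were examined.

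The rule named, in each comparison, up to 8 higher and 8 lower genes with the largest fold change among those past the threshold that had a symbol, a mean log2 CPM of at least 3 and the same direction in every pair of the same mare. For the difference of effects it named up to 5 per direction, without the pair condition. Where fewer than 5 genes passed, the 5 with the smallest p were given as values. Up to 4 genes with the smallest p were named per described list, and ESR1, PGR, PTGS2, OXTR, FOXA2, EPCAM and VIM were given where tested. PTGS2, OXTR and FOXA2 passed the count filter in no comparison. A few genes that met the rule or ranked high are not reported here.

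Pregnant and cyclic libraries with the same letter came from the same mare, so the letters paired them by design. In the data, the correlation of same-mare deviations from the group means lay between -0.00753 and 0.0522 over the 8 epithelial pairs, and 5 of the 8 cyclic libraries correlated best with the pregnant library of their own mare. Fits with the mare as block were therefore made as alternatives to both epithelial pregnancy comparisons. The luminal one left out mare J, which had no pregnant library.

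The settings also tried were DESeq2 1.42.0, DESeq2's relative log expression (RLE) factors within edgeR, no filter or a filter on a count in every library, limma-voom with quality weights, a likelihood ratio test, a joint fit of all 21 libraries, and limma-trend on the deposited signal tables with pseudocounts of 0.5 and 2. Other designs of the block and leaving out each replicate in turn were also tried. Leaving out the ribosomal RNA genes, robust dispersions and leaving out libraries with an unusual content were added after the data were seen. With RLE factors the median log2 fold change of all genes shifted by 0.152 in luminal epithelium, -0.128 in glandular epithelium, -0.24 in stroma, -0.291 in the difference of effects and 0.279 in stroma against glandular epithelium.

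The procedure was tested on simulated data with 200 changed genes per comparison, drawn from the means and library sizes of the real data. At a log2 change of 4 it recovered 46.4% of the changed genes tested in luminal epithelium, 42.9% in glandular epithelium, 0% in stroma, 0% for the difference of effects, 76.9% between the epithelia, 17.7% between stroma and luminal epithelium and 5.56% between stroma and glandular epithelium. At a log2 change of 6 these shares were 90%, 92.6%, 2%, 28.3%, 100%, 44.4% and 45.5%. Between 0 and 3 unchanged genes were called per comparison, no changed gene was called in the wrong direction, and 0 of 20 unchanged lists were called. The counts were drawn independently for each gene at the trended dispersion, without mare effects, unusual libraries or correlation between genes. Few false calls were thus built into the simulation, and their number does not bound false calls in the real data. A list whose genes were truly raised passed with the preset correlation in all 7 comparisons, and with an estimated correlation in the 2 epithelial pregnancy comparisons alone, where its adjusted p was 0.0228 (luminal) and 0.00652 (glandular).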

Results

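The data set held 21 libraries of laser-captured horse endometrium from 5 mares on day 12 of pregnancy or of the estrous cycle. The luminal epithelium lines the uterine cavity and faces the conceptus, the glandular epithelium secretes into it, and the stroma lies between them. Luminal libraries numbered 5 cyclic and 4 pregnant, glandular libraries 4 and 4, and stromal libraries 2 and 2. Total counts ranged from 324704 to 1382614 in cyclic and from 136259 to 440188 in pregnant luminal libraries. They ranged from 222623 to 1079351 in cyclic and from 486316 to 1467510 in pregnant glandular libraries, and from 138441 to 241309 in cyclic and 202545 to 1175127 in pregnant stromal libraries. The libraries detected between 4072 and 11798 genes.

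**Figure D1:**
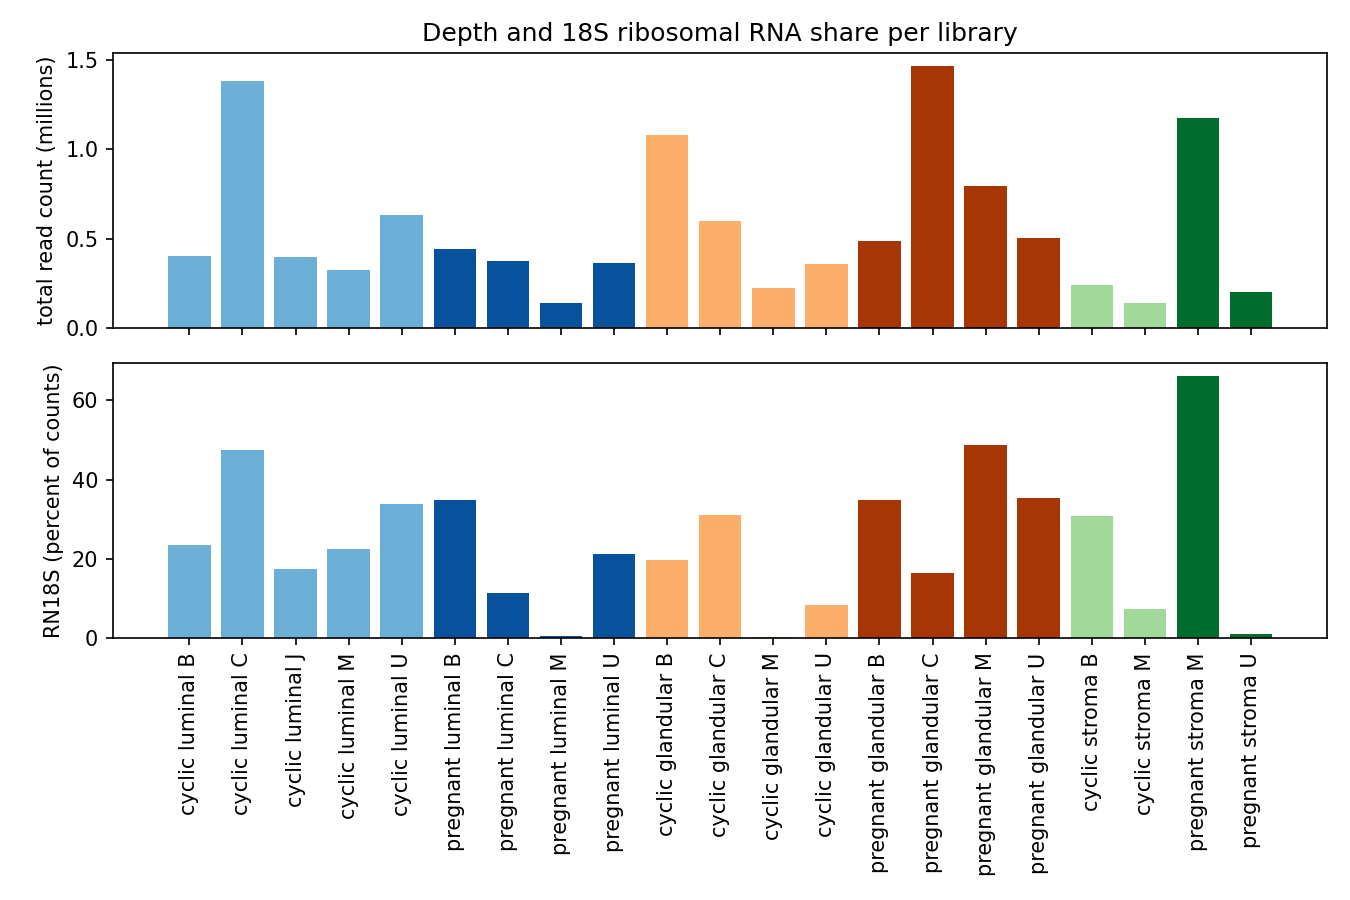
Bars show the total read count and the percent of counts on RN18S (18S ribosomal RNA) in each of the 21 libraries, grouped by compartment and state and lettered by mare. Total counts spanned 136259 to 1467510, and the RN18S share spanned 0.293% to 66.2%.

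RN18S, the gene of 18S ribosomal RNA, took a share of the counts that varied between libraries of 1 group. It was 28.9% ± 12 (SD, n = 5) in cyclic and 17% ± 14.6 (n = 4) in pregnant luminal epithelium, and 14.8% ± 13.4 (n = 4) in cyclic and 33.8% ± 13.4 (n = 4) in pregnant glandular epithelium. The difference between the states gave p = 0.23 in luminal and p = 0.0857 in glandular epithelium (exact permutation tests, two-sided, 2 comparisons). These tests exchanged libraries between mares, although mares B, C, M and U gave both states. Across 9789 genes, log2 CPM of libraries of the same group correlated with a median r of 0.485 (30 pairs of libraries, range 0.377 to 0.709), against 0.375 between compartments of the same biopsy (16 pairs) and 0.382 between compartments of different biopsies (124 pairs). Genes are not independent replicates, so these values describe similarity alone. On the second principal component (9.51% of the variance) all luminal libraries lay above 0 and all glandular and stromal libraries below 0. On the first component (15.7%) 3 of the 4 stromal libraries lay at 119 to 166 and the pregnant stromal library of mare M at -2.16, while the pregnant luminal and the cyclic glandular library of mare M lay at 114 and 87.4.

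**Figure D2:**
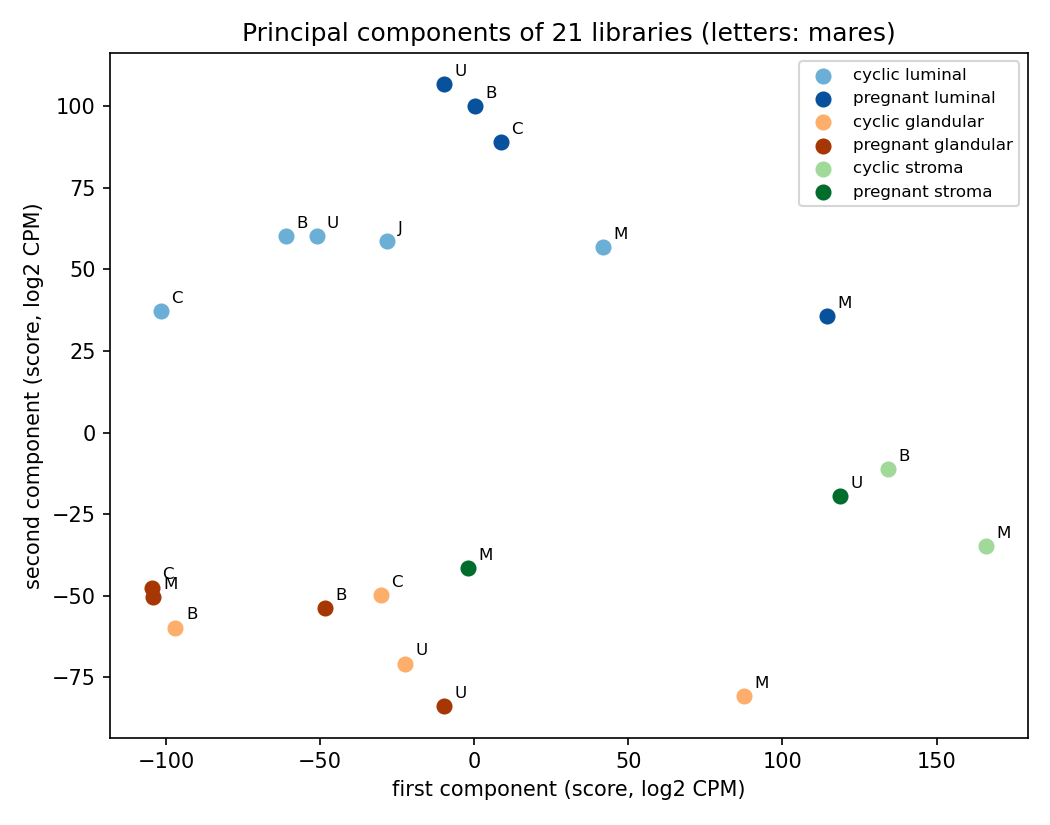
Each point is 1 of the 21 libraries, placed by its first principal component (15.7% of the variance) and its second (9.51%), coloured by compartment and state, with the letter of the mare. Luminal libraries lie above 0 on the second component and glandular and stromal libraries below 0.

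The first comparison asked how the luminal epithelium differs between a uterus that holds a conceptus and a cyclic uterus on the same day. In the main analysis the pregnant luminal libraries of day 12 held more mRNA of AQP1, a water channel, and of CD55, an inhibitor of complement activation. AQP1 rose by a log2 fold change of 5.45 ± 1.05 (578 ± 650 CPM, n = 4, against 12.8 ± 15.2 CPM, n = 5; adjusted p = 0.000737). It stood at 1485 CPM in pregnant B, 608 CPM in U, 167 CPM in M and 51.6 CPM in C, against 37.1 CPM in cyclic J. CD55 rose by 4.92 ± 0.99 (625 ± 478 against 20.5 ± 38.5 CPM, adjusted p = 0.00142). FGF9, a growth factor, rose by 3.90 ± 0.95 (585 ± 469 against 38.5 ± 42.5 CPM, adjusted p = 0.0214). In mare M it stood at 6.42 CPM in pregnancy and 3.70 CPM in the cycle. Both lay under the level of 3 counts in those libraries, so mare M showed no clear rise. SEMA3G, a secreted semaphorin, fell by 3.51 ± 0.88 on the log2 scale (58.2 ± 58.7 against 675 ± 292 CPM, adjusted p = 0.0283). Of the 12 luminal genes that met the naming rule, these among them, 0 kept their call without the pregnant library of mare B. The same held in the joint fit of 21 libraries and in each fit of the deposited signal.

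In total 19 of 4344 genes passed the threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 15 higher and 4 lower in pregnancy, and 16 of them moved the same way in all 4 mare pairs. The other rising genes named by the rule were CRYAB, a small heat shock protein (4.32 ± 1.10), TMEM213 (4.02 ± 0.93), ATP6V0A4, a subunit of the vacuolar proton pump (3.94 ± 1.02; 481 ± 273 against 30.9 ± 28.4 CPM), BCAP29 (3.92 ± 0.94) and PIP4K2C, a lipid kinase (2.85 ± 0.76). Their adjusted p lay between 0.0138 and 0.0482. DOCK8, an activator of a small GTPase, fell by 4.10 ± 1.09 on the log2 scale (adjusted p = 0.0482). RPS6KA3, a ribosomal S6 kinase, held 1 count in the pregnant libraries, and its CPM ratio of cyclic to pregnant was 184 (95% counting interval 32.8 to 7280; adjusted p = 0.0369). Chosen after its values were seen, LOC100052045, which has a placeholder for a symbol, had the smallest adjusted p (0.000203; 6.81 ± 1.22). EPCAM, an epithelial adhesion molecule, had a log2 fold change of 0.44 ± 0.64, VIM, an intermediate filament of mesenchymal cells, 0.24 ± 0.75, and ESR1, the estrogen receptor, -0.19 ± 1.48 (adjusted p = 0.973, 0.987 and 0.993).

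**Figure D3:**
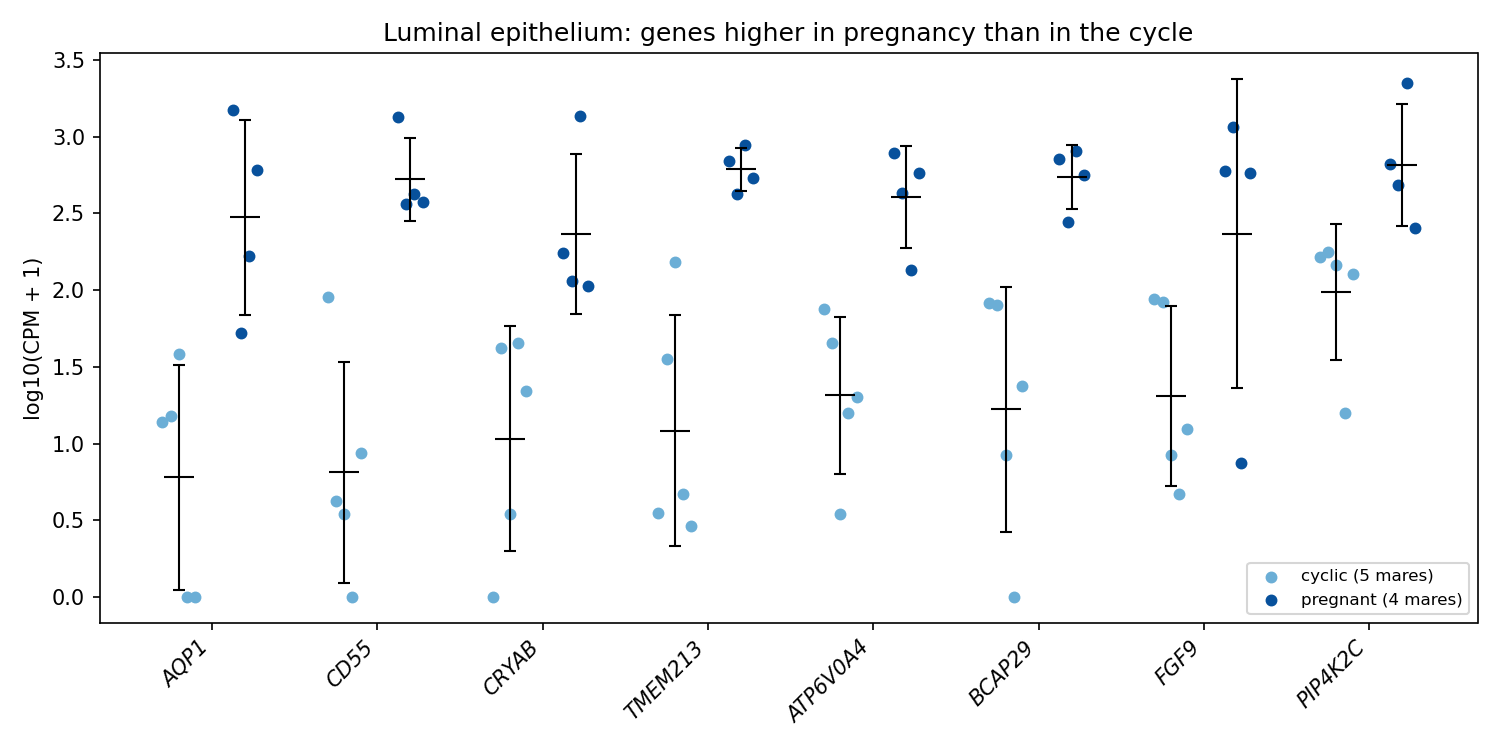
Points are single libraries (cyclic 5 mares, pregnant 4 mares) for the 8 rising genes named by the rule in luminal epithelium, on a scale of log10(CPM + 1), and black lines give mean ± SD. AQP1, CD55, CRYAB, TMEM213, ATP6V0A4, BCAP29, FGF9 and PIP4K2C were higher in pregnancy.

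Of the 23 gene lists tested in luminal epithelium, 5 were called by camera with the preset correlation, and none with an estimated one. Of 19 interferon-stimulated genes, 0 passed over all genes tested and 0 adjusted over the list alone. Yet 14 had positive fold changes, and the list as a whole lay above the other genes (camera adjusted p = 0.00606 and adjusted p = 0.36 with an estimated correlation). Its members with the smallest p were IFI44L (4.75 ± 1.75), LGALS3BP (3.79 ± 1.40) and GBP5 (3.47 ± 1.44), with edgeR adjusted p of 0.307 to 0.424. Of 13 immediate early and heat shock genes, 0 passed over all genes, and 6 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.00606 and adjusted p = 0.156 with an estimated correlation). They included the heat shock proteins HSPB1 (2.92 ± 0.93) and HSPA8 (1.58 ± 0.57), IER3 (1.98 ± 0.70) and, in the other direction, CCN2, a matricellular protein (-1.95 ± 0.68). Of 6 gland-associated genes, 0 passed over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.00606 and adjusted p = 0.156 with an estimated correlation). These were the protease PRSS23 (4.23 ± 1.24) and the secreted uterine serpin SERPINA14 (2.31 ± 0.73, with 1052 ± 485 against 213 ± 255 CPM). Of 22 nuclear genes of oxidative phosphorylation, 17 had positive fold changes and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0318 and adjusted p = 0.156 with an estimated correlation). ATP5F1B stood at 1.84 ± 0.74 and UQCRB at 3.55 ± 1.63. Of 7 matrix remodelling enzymes and inhibitors, 0 passed over all genes, and 1 fell adjusted over the list alone (camera adjusted p = 0.0318 and adjusted p = 0.156 with an estimated correlation). It was the matrix metalloproteinase MMP26 (-3.67 ± 0.99, with 37.6 ± 45.7 against 489 ± 138 CPM).

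Uterine secretory proteins as a list did not pass in luminal epithelium (21 tested, 1 higher over all genes, 3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.253). Besides FGF9 and SERPINA14, the third was STC1, a secreted glycoprotein hormone, at 9743 ± 4022 CPM in pregnancy against 3192 ± 1146 CPM in the cycle (1.61 ± 0.48; edgeR adjusted p = 0.103 over all genes and 0.00869 over the list alone). Of 8 complement genes, 1 rose over all genes (CD55), and CD46, a further inhibitor, fell adjusted over the list alone (-2.89 ± 0.82; list adjusted p = 0.002; camera adjusted p = 0.623). The remaining 18 lists gave camera adjusted p of 0.0606 to 0.886, the former for 73 ribosomal protein genes, which passed with the mare as block (0.00167) but had adjusted p = 0.774 with an estimated correlation and no block. Beside these groups, summed marker levels (CPM without ribosomal RNA genes or TMM scaling) in pregnant and cyclic luminal libraries were 4020 ± 2640 against 2140 ± 1050 CPM for stromal fibroblasts, 4380 ± 1490 against 3990 ± 759 CPM for ciliated cells and 281 ± 308 against 691 ± 380 CPM for macrophages and dendritic cells. The mean total count was 328851 in pregnant and 628211 in cyclic luminal libraries.

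Leaving out 1 library at a time moved the 19 luminal calls to 2 without pregnant B, 30 without pregnant C, 37 without pregnant M, 9 without cyclic B, 10 without cyclic C, 4 without cyclic M and 7 without cyclic U. The mare as block, in a fit without mare J, gave 12 and DESeq2 83. Of the 12 luminal genes that met the naming rule, 6 lost their call in that block fit. Leaving out cyclic J without a block gave 15 calls and also took the call from 6 of the 12. The losses could therefore not be assigned to the block alone. Without pregnant M, the camera adjusted p was 0.0624 for oxidative phosphorylation and 0.23 for matrix remodelling, while uterine secretory proteins (0.0461) and epithelial markers (0.0336) passed as higher in pregnancy. With an estimated correlation, run with all libraries, the latter lists had adjusted p = 0.733 and 0.741.

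In the glandular epithelium the same question met few differences. The main secretory genes were high in both states: P19, uterocalin, a lipid carrier secreted by equine glands, stood at 31440 ± 19390 CPM in pregnancy and 23330 ± 12360 CPM in the cycle (n = 4 each; log2 fold change 0.43 ± 0.77). SPP1, osteopontin, an adhesive secreted glycoprotein, stood at 1113 ± 259 against 4703 ± 6411 CPM (-2.08 ± 0.77; adjusted p = 0.359). COP1, an E3 ubiquitin ligase, fell by 5.60 ± 1.18 on the log2 scale (10.5 ± 11.1 against 556 ± 933 CPM, adjusted p = 0.0133).

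By edgeR's quasi-likelihood test 3 of 4816 genes passed in glandular epithelium, 2 higher and 1 lower, and none moved the same way in all 4 mares, with 350 genes at an unadjusted p under 0.05. The higher ones were gene IDs without a symbol, 102148542 (7.40 ± 1.35; adjusted p = 0.00173) and 102148569 (6.88 ± 1.29; adjusted p = 0.00173). Both rested on the pregnant glandular library of mare M, with 19810 and 78670 CPM against at most 56.1 and 281 CPM in the other 3 pregnant libraries, and without it their log2 fold changes were -0.115 and -0.264. COP1 reached 1950 CPM in the cyclic glandular library of mare M against at most 199 CPM in the other 3 cyclic libraries. Without that library the log2 fold change of COP1 was -3.06 and did not pass (edgeR adjusted p = 1). The COP1 call held under 10 of 19 other settings. It also ended without pregnant M, with RLE factors and with the mare as block, and limma-voom gave the smallest fall (-2.33). The next genes by p were RN28S, 28S ribosomal RNA (4.38 ± 1.02; adjusted p = 0.0525), and PALMD (-4.74 ± 1.14; adjusted p = 0.072). RN28S was -0.42 without the pregnant library of mare M, and without the cyclic library of mare M PALMD was -1.17 and EPCAM -0.21. EPCAM (-1.95 ± 0.76), ESR1 (-0.13 ± 0.89), the progesterone receptor PGR (0.20 ± 1.39) and VIM (0.12 ± 1.09) had adjusted p of 0.407 or more.

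Of 74 ribosomal protein genes in glandular epithelium, 53 had negative fold changes and 0 passed over all genes or adjusted over the list alone. The list lay below the other genes (camera adjusted p = 0.00107 and adjusted p = 0.762 with an estimated correlation). RPL34 stood at -2.27 ± 0.79 and RPS27L at -2.55 ± 0.93. Of 9 genes of the WNT pathway, 8 had positive fold changes and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0376 and adjusted p = 0.762 with an estimated correlation; 0.0713 with the mare as block). The receptor FZD4 (4.50 ± 1.64), the coreceptor LRP5 (3.19 ± 1.48) and the transcription factor LEF1 (2.74 ± 1.13) had the smallest p. Both list calls were lost without the cyclic glandular library of mare M (0.804 and 0.577), and that of the WNT list also without the pregnant one (0.105). The other 18 lists gave camera adjusted p of 0.304 to 0.983. Beside these lists, the RN18S share was 33.8% ± 13.4 in pregnant and 14.8% ± 13.4 in cyclic glandular libraries.

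The 3 glandular calls became 0 with RLE factors or with the mare as block. DESeq2 called 0 genes, but gave none of these 3 an adjusted p. Leaving out 1 library gave 22 without cyclic B, 27 without cyclic C, 5 without cyclic M, 28 without cyclic U, 5 without pregnant B, 10 without pregnant C, 0 without pregnant M and 11 without pregnant U.

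In the stroma, with 2 libraries per state, no gene passed by edgeR's quasi-likelihood test (0 of 2212; 88 genes at an unadjusted p under 0.05; smallest adjusted p = 0.999), and DESeq2, limma-voom and edgeR's likelihood ratio test also called 0. Values of the genes with the smallest p were as follows. PRICKLE2, a planar polarity gene, had 615 ± 179 CPM in pregnant and no count in cyclic stroma, and was at least 80.3-fold higher against the floor of 7.67 CPM for 3 counts over the group. DPYSL2, a cytoskeletal regulator, had 520 ± 491 CPM against no count (at least 67.8-fold higher). LRR1 had a log2 fold change of 6.19 ± 1.78 and RSF1, a chromatin remodelling factor, 5.08 ± 1.81. CCT5, a chaperonin subunit, had 3 counts in pregnant stroma and a ratio of cyclic to pregnant of 126 (95% counting interval 42.5 to 615). ESR1 stood at 540 ± 583 against 10.5 ± 2.48 CPM (5.63 ± 2.50; edgeR adjusted p = 0.999), VIM at 0.76 ± 1.20 and EPCAM at -0.12 ± 2.54. None of 18 lists was called by camera (adjusted p from 0.816 to 0.929). In simulated data of this size 1 of 50 genes changed by a log2 of 6 was recovered, so differences of this size were not detectable here. Without pregnant M 1 gene passed, and without pregnant U 2 genes, where the lone pregnant library was assumed to vary like the cyclic ones.

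Whether pregnancy acted differently on the epithelia was tested as the difference of the effects, glandular minus luminal, in 16 libraries. RN18S was the only gene of 6884 past the threshold (3.64 ± 0.35; edgeR adjusted p = 4.46e-22), with 381 genes at an unadjusted p under 0.05. The RN18S call ended with DESeq2 (adjusted p = 0.126) and with edgeR's likelihood ratio test (adjusted p = 0.283), and DESeq2 called 78 other genes. It also ended with robust dispersions (edgeR adjusted p = 0.886) and with a count in every library (0.585). Without mare M the difference was 1.67 log2 units and still passed. None of the 19 luminal pregnancy genes passed this test, with adjusted p of 0.867 to 0.92. In simulated data the test recovered 0% of genes with a log2 difference of 4 and 28.3% of those with 6. Genes that did not pass were therefore not shown to respond alike in both epithelia. The next genes by p were UBXN6 (14.1 ± 3.95), 102150482 (12.7 ± 3.64), KCNK1, a potassium channel (-6.25 ± 1.79), and RPS6KA3 (10.9 ± 3.31). Their adjusted p ran from 0.827 to 0.867. EPCAM (-1.36 ± 0.97), PGR (3.46 ± 3.17), ESR1 (0.74 ± 1.85) and VIM (-0.06 ± 1.5) had adjusted p of 0.888 or more. Across 3353 genes tested in both epithelia, the pregnancy fold changes correlated with r = -0.0698 and rho = -0.0696, where genes are not independent replicates. None was called in both, and 4 of 7 luminal genes tested in glandular epithelium had the same sign there.

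Of 23 lists, 5 lay below the other genes in this difference of effects, whose median over all genes was 1.28 log2 units, and 0 of their members passed over all genes or adjusted over the list alone. They were 75 ribosomal protein genes (median -0.95; camera adjusted p = 7.24e-09 and adjusted p = 0.118 with an estimated correlation) and 35 genes of oxidative phosphorylation (-0.81; 0.0115 and adjusted p = 0.36 with an estimated correlation). Further lists were 15 immediate early and heat shock genes (-0.11; 0.0327 and adjusted p = 0.36 with an estimated correlation), 14 ciliated cell markers (-0.76; 0.033 and adjusted p = 0.36 with an estimated correlation) and 13 genes of antigen presentation (-0.30; 0.0497 and adjusted p = 0.394 with an estimated correlation). Examples were RPL9 (-2.47 ± 0.88), COX6C (-4.50 ± 2.01), HSPB1 (-4.67 ± 1.73), DNAH5 (-2.62 ± 1.79) and B2M (-1.88 ± 1.03). Without mare M the ribosomal list kept a camera adjusted p of 0.000133, and the others had 0.095 (oxidative phosphorylation), 0.086 (stress genes), 0.095 (ciliated cells) and 0.179 (antigen presentation). Without the ribosomal RNA genes antigen presentation had 0.0611. The other 18 lists gave 0.0571 to 0.961.

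The luminal and the glandular epithelium differed in 498 of 7174 genes. Glandular epithelium carried the secretory transcripts SPP1 and P19. SPP1 was 2078 ± 1100 CPM in glandular and 24.9 ± 8.84 CPM in luminal epithelium (n = 4 mares each; log2 luminal over glandular -6.30 ± 0.49; adjusted p = 4.35e-34). P19 was 26670 ± 14530 against 1987 ± 949 CPM (-3.74 ± 0.33; adjusted p = 2.74e-26). Luminal epithelium carried STC1 at 4933 ± 1399 against 261 ± 74.3 CPM (4.24 ± 0.39; adjusted p = 7.48e-25) and CD74, the invariant chain of class II antigen presentation, at 3587 ± 1704 against 256 ± 69.2 CPM (3.71 ± 0.39; adjusted p = 1.27e-18). TRPV6, an epithelial calcium channel, stood at 904 ± 616 against 30.9 ± 27.4 CPM (5.18 ± 0.54; adjusted p = 6.84e-19).

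By edgeR's quasi-likelihood test with the mare as block, 236 genes were higher in luminal and 262 higher in glandular epithelium, and 484 of the 498 had the same direction in all 4 mares (1086 genes at an unadjusted p under 0.05). The largest rises named by the rule included TMEM213 (7.90 ± 1.13; 212 ± 76.6 against 0.94 ± 1.21 CPM, adjusted p = 4.7e-10) and ATP6V0A4 (7.79 ± 1.25; 177 ± 118 against 0.72 ± 0.62 CPM, adjusted p = 5.25e-08). The amino acid transporter SLC36A2 had 1 glandular count and a ratio of 376 (95% counting interval 66.8 to 14900), and GZMA, a protease of cytotoxic lymphocytes, 1 glandular count and a ratio of 263 (46.6 to 10400). Of the genes of motile cilia, DNAAF11, ENKUR and CFAP95 had no glandular count and were at least 75-fold, 61-fold and 60.1-fold higher in luminal epithelium, against 3 counts over the group, and CFAP206 had a ratio of 251 (44.5 to 9980). On the glandular side, AQP2, a water channel, had 70.5 ± 35.3 CPM and no luminal count (at least 90.4-fold lower in luminal epithelium; adjusted p = 0.000927). The peptide hormone SPX had 2 luminal counts and a ratio of glandular to luminal of 162 (44.7 to 1350), and HEPACAM 2 counts and a ratio of 106 (29.1 to 880). GADD45G, SRXN1, THNSL2 and ELOVL3 had 1 luminal count each and ratios of 216 (38.4 to 8550), 188 (33.4 to 7440), 179 (31.8 to 7080) and 162 (28.9 to 6440). The thiamine transporter SLC19A2 had 2 luminal counts and a ratio of 98 (26.9 to 814). The adjusted p of these low-count genes ran from 0.000719 to 0.0218. EPCAM (-1.67 ± 0.39; adjusted p = 0.000591) and ESR1 (-2.19 ± 0.68; 69.5 ± 47.6 against 277 ± 95.3 CPM, adjusted p = 0.0224) were lower in luminal epithelium. VIM (1.66 ± 0.58; adjusted p = 0.055) and PGR (-2.90 ± 1.49; adjusted p = 0.337) did not pass.

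**Figure D4:**
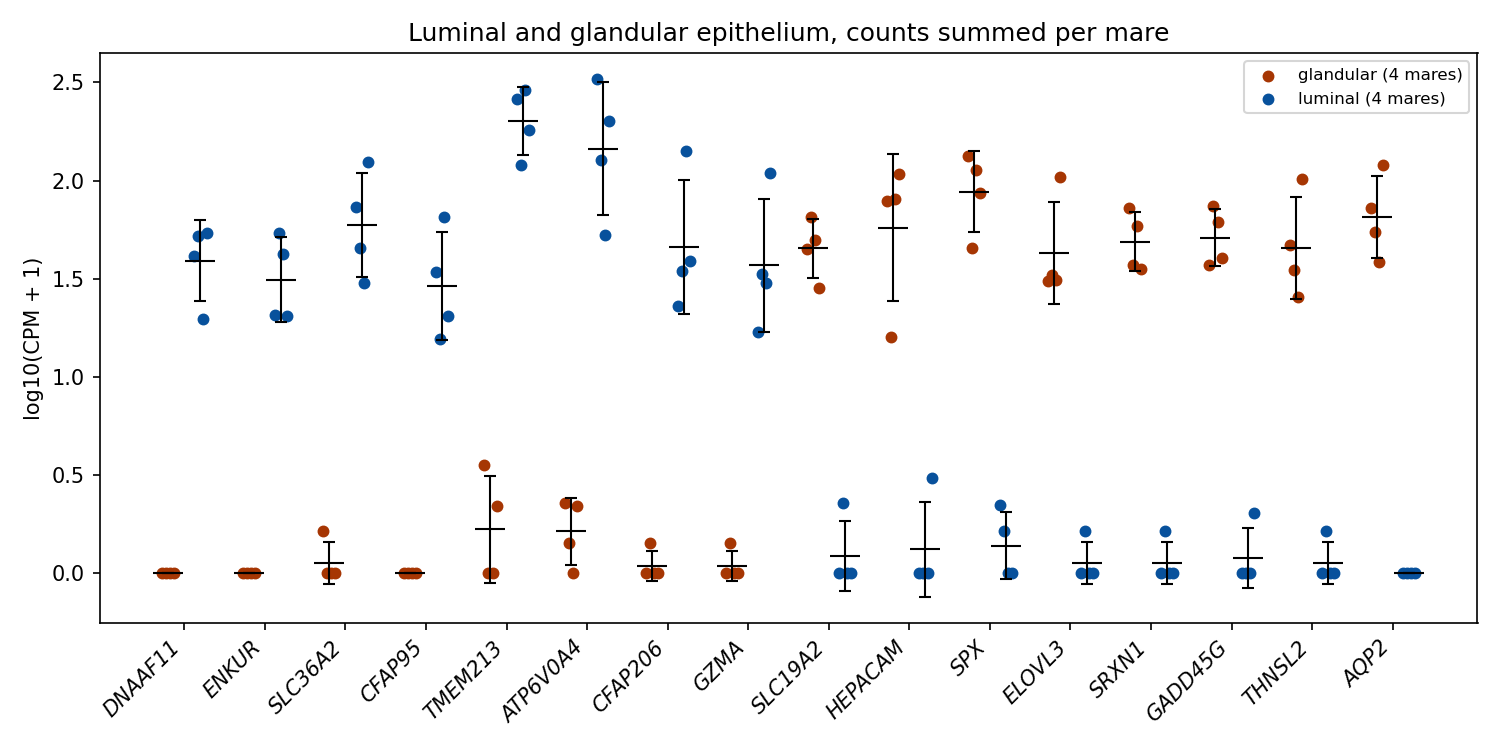
Points are the 4 mares for the 16 genes named by the rule between luminal and glandular epithelium, from counts summed per mare, on a scale of log10(CPM + 1), and black lines give mean ± SD. TMEM213 and ATP6V0A4 lie near 0 in glandular epithelium, and AQP2 and SPX near 0 in luminal epithelium.

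Camera with the preset correlation called 12 of 24 lists between the epithelia, 10 higher in luminal and 2 higher in glandular epithelium, and none with an estimated correlation. All 14 ciliated cell markers were on the luminal side, 9 past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 3.14e-14 and adjusted p = 0.0816 with an estimated correlation). FOXJ1, the transcription factor of motile cilia, stood at 480 ± 203 against 42.5 ± 44.9 CPM (4.19 ± 0.67), and the axonemal genes DNAH9 and SPAG17 at 4.28 ± 0.61 and 5.28 ± 0.93. Of 16 genes of ion and water transport, 5 were higher and 2 lower over all genes, and 10 and 2 adjusted over the list alone (camera adjusted p = 6.48e-05 and adjusted p = 0.11 with an estimated correlation). TRPV6 was higher in luminal epithelium, and AQP2 and SLC12A2, a sodium, potassium and chloride cotransporter (-3.29 ± 0.43; 178 ± 30.5 against 1762 ± 469 CPM), in glandular epithelium. Of 25 uterine secretory proteins, 8 were higher in luminal and 4 in glandular epithelium over all genes, and 9 and 4 adjusted over the list alone (camera adjusted p = 0.000393 and adjusted p = 0.17 with an estimated correlation). SERPINA14 was on the luminal side (5.35 ± 0.68, with 484 ± 300 against 9.69 ± 2.84 CPM).

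Lists of immune-related genes lay above other genes in luminal epithelium with the preset correlation, and none passed with an estimated one (adjusted p = 0.11 to 0.403). Summed markers of immune cells (CPM without ribosomal RNA genes or TMM scaling), which were not tested, differed by class. Those of T and NK cells were 384 ± 194 CPM in cyclic and 566 ± 355 CPM in pregnant luminal epithelium, against 99.4 ± 62.9 and 84.8 ± 93.3 CPM in glandular epithelium. Those of macrophages and dendritic cells were 691 ± 380 and 281 ± 308 CPM, against 80.8 ± 58.4 and 94.3 ± 89.7 CPM. Markers of B and plasma cells were 298 ± 259 and 75.5 ± 83.6 CPM, against 121 ± 140 and 138 ± 226 CPM, and those of neutrophils and mast cells 12.5 ± 12.6 and 11.4 ± 20.5 CPM, against 26.8 ± 47.8 and 44 ± 35 CPM. Of 22 interferon-stimulated genes, 3 were higher over all genes, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.53e-06 and adjusted p = 0.11 with an estimated correlation). The higher ones over all genes were OAS2 (4.60 ± 1.04), LGALS3BP (6.20 ± 1.64) and MX1 (4.68 ± 1.57). Of 7 complement genes, 5 were higher and 1 lower over all genes and adjusted over the list alone (camera adjusted p = 6.48e-05 and adjusted p = 0.11 with an estimated correlation). The inhibitors CD55 (4.55 ± 0.91), SERPING1 (4.94 ± 1.07) and CD46 (2.35 ± 0.55) were among the higher ones. Of 14 genes of antigen presentation, 3 were higher over all genes, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0446 and adjusted p = 0.403 with an estimated correlation). CD74 and the class II chain DRA (2.76 ± 0.58) were higher. Of 14 immediate early and heat shock genes, 4 were higher over all genes and 5 adjusted over the list alone (camera adjusted p = 3.5e-05 and adjusted p = 0.11 with an estimated correlation). EGR1 (4.75 ± 0.84), CCN2 (4.31 ± 0.53) and IER3 (4.69 ± 0.73) were among them.

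Of 30 extracellular matrix genes, 4 were higher in luminal epithelium over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00267 and adjusted p = 0.16 with an estimated correlation). They included the collagens COL1A1 (2.87 ± 0.52) and COL12A1 (3.92 ± 0.82) and the basement membrane laminin LAMB3 (4.82 ± 1.43). Of 13 stromal fibroblast markers, 1 was higher over all genes and 2 adjusted over the list alone, COL1A1 and VIM (camera adjusted p = 0.041 and adjusted p = 0.213 with an estimated correlation). Of 6 prostaglandin genes, 2 were higher over all genes and adjusted over the list alone, the prostaglandin reductase PTGR1 (4.13 ± 0.94) and PTGFRN (6.70 ± 2.20). The camera adjusted p was 0.0245 (adjusted p = 0.403 with an estimated correlation), 0.131 without the ribosomal RNA genes and 0.172 without the libraries of mare M absent from the table of 19 libraries.

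On the glandular side stood the secretory pathway and ribosomal proteins. All 38 genes of the unfolded protein response and secretory pathway had lower luminal levels, 5 past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 2.53e-06 and adjusted p = 0.11 with an estimated correlation). P4HB, a protein disulfide isomerase, was at -1.72 ± 0.41, SEL1L at -1.81 ± 0.54 and XBP1, a transcription factor of secretory cells, at -2.18 ± 0.65. Of 75 ribosomal protein genes, 18 were lower in luminal epithelium over all genes and 28 adjusted over the list alone (camera adjusted p = 5.66e-09 and adjusted p = 0.11 with an estimated correlation). RPS13 (-2.04 ± 0.42) and RPL31 (-1.51 ± 0.36) were examples. Gland-associated genes split: of 8, 2 were higher and 3 lower in luminal epithelium over all genes, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.509). The chemokine CXCL14 (-5.04 ± 0.79) and the homeobox gene MSX1 (-2.65 ± 0.54) stood on the glandular side. Of 10 WNT pathway genes, LEF1 (-5.46 ± 1.18) and AXIN2 (-5.29 ± 1.35) were lower in luminal epithelium over all genes (camera adjusted p = 0.135). The 12 lists not called, these among them, gave adjusted p of 0.0628 to 0.757.

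Without mare B 230 genes passed between the epithelia and without mare C 280, and the cyclic biopsies alone gave 120 and the pregnant ones alone 130. Without the pregnant glandular library of mare M 266 genes passed, DESeq2 called 1009, and fits of unsummed libraries gave 247 with the biopsy and 279 with the mare as block.

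Among the genes past the threshold between stroma and luminal epithelium in 3 mares were COL14A1, IGFBP5 and DCN, higher in stroma, and TRPV6 and STC1, lower in stroma. COL14A1, a fibril-associated collagen, was 1248 ± 665 CPM in stroma and 5.16 ± 4.49 CPM in luminal epithelium (n = 3 each; 7.86 ± 1.33; adjusted p = 5.87e-06). IGFBP5, which binds insulin-like growth factors, was 1534 ± 395 against 14.5 ± 1.46 CPM (6.66 ± 1.18; adjusted p = 1.32e-05), and the matrix proteoglycan DCN 1130 ± 324 against 35.6 ± 54.3 CPM (6.42 ± 1.39; adjusted p = 0.000761). TRPV6 was 12.5 ± 6.63 CPM in stroma against 1424 ± 1159 CPM (-6.54 ± 1.20; adjusted p = 2.83e-05), and STC1 150 ± 119 against 4890 ± 1943 CPM (-5.26 ± 0.97; adjusted p = 2.83e-05).

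By edgeR's quasi-likelihood test 61 of 3512 genes passed, 20 higher and 41 lower in stroma, all in the same direction in the 3 mares (362 genes at an unadjusted p under 0.05). Further genes named by the rule were ABCA8 (6.82 ± 1.34), the proteinase inhibitor TIMP2 (6.71 ± 1.38) and the matrix protein FBLN1 (6.84 ± 1.68) on the stromal side, with adjusted p of 0.000142 to 0.00536. JAM2, a junctional adhesion molecule, had 2 luminal counts and a ratio of 222 (95% counting interval 61 to 1840), and CREB5, a transcription factor, 1 and a ratio of 355 (63.2 to 14100). On the luminal side UNC5CL stood at -6.70 ± 1.33 (adjusted p = 0.000172). Genes with 1 to 3 stromal counts were PADI2 (ratio of luminal to stroma 327, 90.3 to 2710), the lipase LIPG (256, 70.7 to 2120), GCNT3, an enzyme of mucin glycosylation (260, 71.7 to 2150), DTHD1 (136, 46.2 to 662), the glucose transporter SLC2A1 (178, 49.1 to 1480) and the axonemal dynein DNAH10 (333, 59.4 to 13200). Their adjusted p ran from 0.000382 to 0.0351. VIM (1.69 ± 0.91), EPCAM (-1.61 ± 1.11) and ESR1 (0.02 ± 4.76) did not pass (adjusted p = 0.531, 0.755 and 1).

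Camera with the preset correlation called 11 of 23 lists between stroma and luminal epithelium, 6 higher and 5 lower in stroma, and none with an estimated correlation. Of 31 extracellular matrix genes, 5 were higher over all genes, and 10 higher and 1 lower adjusted over the list alone. Of 13 fibroblast markers 3 were higher over all genes and 6 adjusted over the list alone, among them GSN (6.05 ± 1.33). Both lists had a camera adjusted p of 2.77e-11 (adjusted p = 0.245 with an estimated correlation). Of 7 smooth muscle and pericyte markers, 1 was higher over all genes, TAGLN (6.17 ± 1.72), and 4 adjusted over the list alone (2.9e-05 and adjusted p = 0.245 with an estimated correlation). Of 11 matrix remodelling genes, TIMP2 alone was higher over all genes and adjusted over the list alone (0.000104 and adjusted p = 0.245 with an estimated correlation). Of 20 growth factors and receptors, 3 were higher over all genes, and 7 higher and 2 lower adjusted over the list alone (0.00127 and adjusted p = 0.45 with an estimated correlation). FST, an activin antagonist (6.01 ± 1.26), and PTN (4.44 ± 0.96) were higher. Of 75 ribosomal protein genes 67 had positive fold changes, such as RPL37A (2.26 ± 0.88), and 0 passed over all genes or adjusted over the list alone (9.35e-11 and adjusted p = 0.45 with an estimated correlation).

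Lower in stroma than in luminal epithelium were the ciliated cell markers, of which all 9 had negative fold changes. DNAH9 (-6.06 ± 1.43) and FOXJ1 (-6.01 ± 1.61) passed over all genes and 4 adjusted over the list alone (camera adjusted p = 5.16e-06 and adjusted p = 0.245 with an estimated correlation). Of 8 tight junction and polarity genes, CLDN8 (-5.20 ± 1.21) and PATJ (-5.44 ± 1.47) were lower over all genes and 4 adjusted over the list alone (0.00411 and adjusted p = 0.45 with an estimated correlation). Of 13 genes of ion and water transport, 1 was lower over all genes, TRPV6, and 3 adjusted over the list alone (0.00695 and adjusted p = 0.45 with an estimated correlation). Of 5 solute transporters, 1 was lower over all genes, SLC2A1, and 2 adjusted over the list alone (0.0322 and adjusted p = 0.45 with an estimated correlation). Of 7 epithelial markers, 0 passed over all genes and 2 were lower adjusted over the list alone, with SPINT2 at -5.00 ± 1.59 (0.0389 and adjusted p = 0.45 with an estimated correlation). The other 12 lists gave camera adjusted p of 0.175 to 0.629. Without the pregnant biopsy of mare M, the camera adjusted p was 0.0593 for solute transporters, 0.0749 for matrix remodelling and 0.225 for epithelial markers. DESeq2 called 474 genes and limma-voom 3 in this comparison, and without mare B 24 genes passed, without mare M 18 and without mare U 36.

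Between stroma and glandular epithelium, SPP1, P19 and EPCAM passed as lower and FST and VIM as higher in stroma. SPP1 was 34 ± 23.1 CPM in stroma against 2175 ± 1199 CPM in glandular epithelium (n = 3 mares each; -6.04 ± 1.06; adjusted p = 6.89e-05). P19 was 2361 ± 1884 against 28220 ± 13560 CPM (-3.85 ± 0.94; adjusted p = 0.0115). FST was 831 ± 356 CPM in stroma against 9.97 ± 9 CPM (6.70 ± 1.32; adjusted p = 0.000778) and VIM 1410 ± 890 against 79.6 ± 20.6 CPM (3.98 ± 1.02; adjusted p = 0.016). EPCAM was lower in stroma (161 ± 82.2 against 1921 ± 1311 CPM; -3.53 ± 0.97; adjusted p = 0.0307).

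By edgeR's quasi-likelihood test 63 of 4830 genes passed, 38 higher and 25 lower in stroma, with the same direction in all 3 mares (480 genes at an unadjusted p under 0.05), and RLE factors gave 48 higher and 16 lower. Of the contractile genes named by the rule, TPM2 had no glandular count (at least 222-fold higher in stroma), TAGLN 3 (ratio 264, 95% counting interval 89.7 to 1290) and MYH11, smooth muscle myosin, 1 (613, 109 to 24300). TM4SF1 had 1 glandular count (655, 117 to 26000), PLAT, tissue plasminogen activator, 2 (256, 70 to 2120) and JAM2 2, with 383 ± 443 CPM in stroma, while EXTL2 stood at 7.01 ± 1.86. Lower in stroma were the amino acid transporter SLC38A1 (-7.21 ± 1.59), the nucleotide sugar transporter SLC35A3 (-6.22 ± 1.66), SOX17, a transcription factor of uterine glands (-6.14 ± 1.70; 8.29 ± 11.3 against 387 ± 131 CPM), and PDXK (-5.78 ± 1.65). WIPF3 and LMTK2 had no stromal count and were at least 100-fold and 91.6-fold lower in stroma, and LRIG1 had 2 and a ratio of glandular to stroma of 139 (38.3 to 1150). The adjusted p of these genes ran from 0.00465 to 0.0489. ESR1 (-1.44 ± 1.44) and PGR (-1.35 ± 2.96) did not pass (adjusted p = 0.855 and 0.922).

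Camera with the preset correlation called 11 of 23 lists between stroma and glandular epithelium, 8 higher and 3 lower in stroma, and none with an estimated correlation. Of 32 extracellular matrix genes, 4 were higher over all genes and 15 adjusted over the list alone (camera adjusted p = 1.64e-19 and adjusted p = 0.162 with an estimated correlation), among them COL14A1 (6.09 ± 1.21) and COL1A1 (4.43 ± 1.08). Of 15 fibroblast markers, 3 were higher over all genes and 11 adjusted over the list alone (4.71e-16 and adjusted p = 0.162 with an estimated correlation). Of 7 smooth muscle and pericyte markers it was 3 and 6 (3.83e-10 and adjusted p = 0.162 with an estimated correlation). Of 6 endothelial markers, 0 passed over all genes and 4 were higher adjusted over the list alone (2.23e-06 and adjusted p = 0.236 with an estimated correlation), with the vascular growth factor receptor FLT1 at 6.83 ± 2.41. Of 12 matrix remodelling genes, 2 were higher over all genes, PLAT and MMP2 (4.18 ± 1.14), and 6 higher and 2 lower adjusted over the list alone (1.98e-05 and adjusted p = 0.219 with an estimated correlation). Of 21 growth factors and receptors, 5 were higher over all genes and 8 adjusted over the list alone (0.000219 and adjusted p = 0.219 with an estimated correlation), including IGFBP7 (5.52 ± 1.33).

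Of 7 complement genes, CLU (5.57 ± 1.38), C1S (3.98 ± 1.08) and C1R (4.68 ± 1.32) were higher in stroma over all genes, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00216 and adjusted p = 0.256 with an estimated correlation). Of 75 ribosomal protein genes, 45 had positive fold changes and 0 passed over all genes or adjusted over the list alone, for example RPLP1 (1.44 ± 0.88). The list lay above the genes as a whole, whose median was -1.07 (0.00294 and adjusted p = 0.602 with an estimated correlation). On the other side, 29 of 33 genes of the unfolded protein response and secretory pathway had negative fold changes and 0 passed over all genes or adjusted over the list alone (0.00194 and adjusted p = 0.236 with an estimated correlation). CALR, a chaperone of the endoplasmic reticulum, stood at -2.65 ± 0.97. Of 9 epithelial markers, 1 was lower over all genes, EPCAM, and 2 adjusted over the list alone (0.0115 and adjusted p = 0.256 with an estimated correlation). Of 10 tight junction and polarity genes, all with negative fold changes, it was 0 and 1, CLDN8 (-4.55 ± 1.43; 0.0372 and adjusted p = 0.357 with an estimated correlation). The other 12 lists gave camera adjusted p of 0.0606 to 0.751. Without mare B 0 genes passed, without mare M 2 and without the pregnant biopsy of mare M 9, while DESeq2 called 526 and limma-voom 251.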

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

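The tests of single libraries and of borrowed spread below were chosen only after the results were seen, as were those of added stromal and glandular RNA, while the test on luminal genes and that of ribosomal reads were written before, and the splits were set by the plan. Libraries or mares that stood apart from the rest of their group were searched for in 104 groups of values, of which 29 had such a value. For normally distributed values the rule marks about 1 in 20 groups (5.2 here). The CPM values were skewed, and a group with 1 value above 0 among zeros is always marked. The number 29 therefore does not show an excess of unusual libraries.

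RN18S was the only gene past the threshold for a difference of the pregnancy effect between the epithelia, at 3.64 log2 units. Per biopsy, the log2 ratio of glandular to luminal RN18S share was -0.25, -0.62, -6.26 and -2.02 in the cycle (mares B, C, M and U) and -0.01, 0.52, 6.75 and 0.75 in pregnancy. An exact permutation test of these ratios gave p = 0.0286 (two-sided), the smallest possible with 4 against 4 biopsies, so it could not tell whether the adjusted p of 4.46e-22 rested on spread borrowed from other genes. That test also exchanged biopsies between mares, although the same mares gave both states. Robust dispersions gave an adjusted p of 0.886, a likelihood ratio test 0.283 and DESeq2 0.126. In mares B, C and U the ratio was also higher in pregnancy, and without mare M the difference was 1.67 log2 units. It still passed, but by the same test, so this could not settle whether the libraries of mare M were the whole cause. Of 35 splits of the 8 biopsies into groups of the same sizes, 13 gave as many called genes as the real one, so chance was not excluded.

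The IDs 102148542 and 102148569 rose in glandular epithelium through the pregnant library of mare M, where they held 9524 and 37820 counts. Without it the larger of their log2 fold changes was -0.115 and the other -0.264, which is consistent with a content of that library alone. The same library held 2.15% RN28S and 7.7% of counts on unmatched IDs. Over the other 20 libraries the share of the IDs and the RN28S share had rho = -0.0165 (permutation p = 0.947, 100000 permutations) and r = 0.123 (p = 0.498; 0.0475 without the 2 farthest libraries), and this could not tell whether ribosomal reads were counted on them. The pregnant stromal library of mare M, with 0.934% RN28S, had 0.0482% on these IDs, and of 35 splits of the glandular libraries 14 gave as many called genes as the 3 of the real one (highest 8), so chance was not excluded.

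For pregnancy in luminal epithelium, 1 of 100 splits that took no account of the mares, the real one, gave as many called genes (19, against at most 6 in the others), and among the 15 of these that parted all 4 mares with both states it was 1 of 15 (highest other 6), too few to judge. Less RNA of other compartments in the pregnant captures would raise luminal genes together, but the upper quartile of the pregnancy fold changes of 233 genes higher in luminal than glandular epithelium was 1.25 log2 units, against 2.30 for the smallest rise called. Of these 233 genes 140 were positive (median 0.281). The median was -0.255 for 133 genes higher in glandular than luminal epithelium and -0.956 for 13 genes higher in stroma than luminal epithelium. A smaller shift of this kind was therefore not excluded. Added RNA of glands or stroma, as captured, cannot raise a gene above its level there. The median level in pregnant luminal libraries lay above the highest of the glandular libraries for 15 of the 15 rising genes. It lay above the highest of the 4 stromal libraries for 14, all but 100146336 (147 against 264 CPM, without ribosomal RNA genes or TMM scaling). These medians argue against such RNA as the whole cause of those rises. They do not bound single libraries or a single cell type of the stroma. AQP1 held 51.6 and 167 CPM (TMM-scaled) in pregnant luminal libraries C and M, and 1485 and 608 CPM in B and U. Its highest stromal level was 264 CPM without that scaling. The shallow pregnant library of mare M was not the cause, as 17 genes stayed past the threshold without it. Without the pregnant library of mare B 1 of the 19 stayed past it. All 19 kept their sign without the library of mare B, with a median absolute log2 fold change of 3.90 (SD 1.23 over the 19 genes) against 4.10 (SD 1.30). The genes were chosen for large changes in these same libraries, so the kept signs and sizes are no independent support. Whether conceptus signals caused the differences was not tested.

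Between luminal and glandular epithelium 1 of 32 splits, the real one, gave 498 genes and the others 0, but 24 of the others parted only 2 of the 4 mares and so held less information. Among splits that parted every mare it was 1 of 8, too few to judge. For stroma against luminal epithelium it was 1 of 10 (61 genes, highest other 0) and against glandular epithelium 1 of 10 (63, highest other 3), again too few to judge.

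The RN28S share was 0.166% in cyclic luminal library C (others 0.00348% to 0.0182%) and 2.15% in pregnant glandular library M (0.0037% to 0.0542%), where RN28S reached 35440 CPM (43.9 to 436 CPM) and unmatched IDs 7.7% (1.83% to 2.73%). Pregnant luminal library M detected 4648 genes (6978 to 7137). In pregnant luminal libraries RPS6KA3 had 2.72 CPM in C (0 in the others), DOCK8 93 CPM in U (0 to 3.28), CD55 1341 CPM in B (362 to 423) and CRYAB 1373 CPM in M (105 to 174). In cyclic luminal libraries CD55 had 89.2 CPM in B (0 to 7.61) and TMEM213 151 CPM in J (1.9 to 34.6). In pregnant glandular library M 102148542 had 19810 CPM (2.51 to 56.1) and 102148569 78670 CPM (4.88 to 281). In cyclic glandular library M COP1 had 1950 CPM (4.86 to 199), PALMD 2016 CPM (2.19 to 84.3) and EPCAM 14350 CPM (1182 to 1595).

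In counts summed per mare, luminal HEPACAM was 2.05 CPM and GADD45G 1.02 CPM in mare U, and SRXN1, THNSL2 and ELOVL3 0.635 CPM and SLC19A2 1.27 CPM in mare C, each with 0 in the other 3 mares. Glandular SLC36A2 was 0.637 CPM in mare B, and CFAP206 and GZMA 0.418 CPM in mare C, with 0 elsewhere. Luminal CFAP206 was 141 CPM in mare M (22.1 to 37.9) and PGR 69.9 CPM in mare C (0 to 8.27), and glandular ELOVL3 was 104 CPM in mare U (29.9 to 32.2) and EPCAM 3588 CPM in mare M (1232 to 1554).

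The test of the difference of pregnancy effects between the epithelia called RN18S (3.64), as weighed above, and, with the preset correlation between genes, 5 lists with these medians: antigen presentation (-0.30), oxidative phosphorylation (-0.81), ciliated cell markers (-0.76), immediate early and heat shock genes (-0.11) and ribosomal proteins (-0.95). None of the 5 passed with an estimated correlation (camera adjusted p = 0.118 to 0.394).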

How the results depend on the processing

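No gene past the threshold both in the main analysis and under another setting had opposite signs in them. For pregnancy in luminal epithelium, 19 genes passed in the main analysis, 83 with DESeq2 (29 up, 54 down), 12 without a filter, 10 with voom, 30 with the likelihood ratio test, 1 in the joint fit of 21 libraries, 0 with each of the 3 fits of the deposited signal. It was 12 with the mare as block and without mare J (8 up, 4 down), 9 of them shared. Leaving out a replicate gave 2 to 37, with the lowest without pregnant B and the highest without pregnant M. In glandular epithelium 3 genes passed in the main analysis, 0 with DESeq2, 0 with RLE factors, 34 without a filter and 5 with a count in every library. There were 6 with voom, 21 with the likelihood ratio test, 7 in the joint fit, 0 with each of the 3 signal fits, 6 with robust dispersions, 0 with the mare as block and 0 to 28 with a replicate left out. Without pregnant glandular replicate M the log2 fold changes of 102148542 and 102148569 turned to -0.115 and -0.264, and without cyclic glandular replicate M they were 9.09 and 8.29. In stroma no gene passed in the main analysis, 2 without a filter, 3 in the joint fit and 0 to 2 with a library left out. No paired analysis was possible because the states shared mare M alone. For the difference of effects, 1 gene passed in the main analysis, 78 with DESeq2, none of them shared, 0 with a count in every library and 2 with the likelihood ratio test. There were 8 without the block, 0 without ribosomal RNA genes, 0 with robust dispersions and 1 with each mare left out. Between the epithelia 498 genes passed in the main analysis, 1009 with DESeq2 (495 shared), 230 to 411 with a mare left out and 247 and 279 for unsummed libraries with the biopsy or the mare as block, 120 in cyclic and 130 in pregnant biopsies and 266 without the pregnant glandular library of mare M. For stroma against luminal epithelium it was 61 in the main analysis, 474 with DESeq2, 29 without a filter, 3 with voom, 201 with the likelihood ratio test, 18 to 36 with a mare left out, 34 for unsummed libraries with either block, 89 without the block, 8 in cyclic and 0 in pregnant biopsies. Against glandular epithelium it was 63 in the main analysis, 526 with DESeq2, 20 without a filter, 251 with voom, 223 with the likelihood ratio test, 0 to 45 with a mare left out, 99 without the block, 3 in cyclic and 0 in pregnant biopsies and 9 without the pregnant biopsy of mare M. The named genes kept past the threshold under every setting that gave them a value were 15 of 80 between the epithelia (54 had one with a count in every library), among them SPP1, P19, STC1, TRPV6, CD74, AQP2, TMEM213 and ATP6V0A4, and 0 in the other comparisons. Of the 80, 48 had a value in each fit of unsummed libraries, 55 in cyclic and 60 in pregnant biopsies alone. Genes without a value were not put to those settings. No list was called with an estimated correlation, and fry kept 2 of 5 list calls in luminal epithelium, 0 of 2 in glandular epithelium, 0 of 5 for the difference of effects (1 gained), 8 of 12 (1 gained) between the epithelia, 0 of 11 for stroma against luminal and 9 of 11 (2 gained) against glandular epithelium. Why the tools differed was not tested.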

Other observations

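The test of the proton pump genes below was set up after the result for 2 of its genes was seen, as was that of the first principal component, and the other values here were not tested. Levels in this part are CPM without ribosomal RNA genes or TMM scaling, except those of ATP6V1C2. By mean level, glandular epithelium (8 libraries) was led by P19 at 35850 ± 21190 CPM (7028 to 72830), followed by the translation factor EEF1A1 (16000 ± 3363 CPM) and by the ID 102148569 (12300 ± 34340 CPM, 6.3 to 97290 CPM). TPT1 (4513 CPM) and CTTNBP2 (4265 ± 1435 CPM) came next. Luminal epithelium (9 libraries) was led by EEF1A1 (7969 ± 2680 CPM), STC1 (6927 ± 4526 CPM) and CD74 (5251 ± 2997 CPM). Stroma (4 libraries) held much EEF1A1 (17480 ± 5757 CPM), TMSB4X (6451 ± 2201 CPM) and the lipocalin APOD (4332 ± 2733 CPM).

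In cyclic and pregnant stroma, summed markers of T and NK cells were 884 ± 666 and 514 ± 129 CPM and those of macrophages and dendritic cells 1140 ± 1130 and 257 ± 144 CPM, beside the epithelial values given above. Markers of B and plasma cells ranged from 42 to 298 CPM by group and those of neutrophils and mast cells from 11.4 to 229 CPM, while red blood cell genes had 0 counts and no ID of the mitochondrially encoded list was found. Ciliated cell markers summed to 750 ± 856 CPM in cyclic glandular, 487 ± 316 CPM in pregnant glandular, 54.3 ± 0.418 CPM in cyclic stromal and 141 ± 5.16 CPM in pregnant stromal libraries. Endothelial markers summed to 2920 ± 396 and 1690 ± 697 CPM in cyclic and pregnant stroma, against 136 to 194 CPM in the epithelial groups.

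Transcripts high in glands had these levels in stroma. P19 was 2903, 2004, 7528 and 1075 CPM, EPCAM 396, 78, 253 and 109 CPM and SPP1 30, 46.8, 95.7 and 29.9 CPM in cyclic B, cyclic M, pregnant M and pregnant U, against 35850, 2759 and 2751 CPM in the mean of the glandular and 2951, 948 and 50.9 CPM in that of the luminal libraries. The origin of these reads was not tested.

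The subunit gene ATP6V0A4 of the vacuolar proton pump was higher in luminal than glandular epithelium, and so was TMEM213. In the main analysis both were also higher in luminal epithelium in pregnancy. These pregnancy calls were lost without the pregnant luminal library of mare B. Between the epithelia the subunit gene ATP6V1C2 was also higher in luminal epithelium (2.84 ± 0.52; 718 ± 163 against 132 ± 110 CPM; edgeR adjusted p = 3.82e-06). The other 12 subunit genes tested had a median log2 fold change of -0.42, 3 were positive and 0 passed the threshold (limma's camera, two-sided, adjusted p = 0.628 over 1 set). A higher level of these 12 as a set was thus not borne out. Their SE ran from 0.809 to 2.2 log2 units, so differences in single subunits were not excluded, and subunit genes that were not tested remain open. Of the water channels, AQP1 rose with pregnancy in luminal epithelium, and AQP2 was counted in glandular epithelium and in no luminal library of the 4 mares compared.

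The first principal component followed the number of genes with a count across the 21 libraries (r = -0.929, rho = -0.93, permutation p = 1e-05 for each; r = -0.939 without the 2 farthest libraries). With all libraries thinned to 128256 counts it explained 13.5% of the variance, and the pregnant stromal library of mare M lay at 6.21 against 92.7 to 117 in the other stromal libraries. Its RN18S share of 66.2% was the highest of all libraries.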
